A study of Homo sapiens with 4 samples.

How the data were processed

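Gene tables of 4 RNA-seq libraries were analysed, 1 each for vector, the library labelled JFK, control siRNA and ING5 siRNA, all labelled HepG2. RNA was isolated with Trizol and sequenced on an Illumina HiSeq instrument, per the labels. Groups were taken from the transfection field of the labels. Per the submitters' processing notes, FastQC, fastp, STAR and DESeq2 were used with the builds GRCh37 and hg19, and versions and roles are not given in the sources used here. The counter that assigned reads to genes is not given in the sources used here either.

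The vector and JFK tables hold deposited expected counts, which need not be whole (68.6% and 69.0% were whole), and deposited FPKM, per the file headers. The siRNA tables hold deposited counts, all whole, and deposited RPKM, per the file headers. In the deposited RPKM columns 0.01 stands for genes with no reads. The deposited FPKM columns hold 0.01 for 749 genes in vector and 791 in the library labelled JFK, of which 724 and 763 have a count of 0. Tables listed only genes above 0 in at least 1 library of their pair, 17010 in the vector pair and 16860 in the siRNA pair. Genes are named by Entrez identifier, which was matched to symbols through a RefSeq gene table of a later build than GRCh37; 16900 and 16769 identifiers matched, while 110 and 89 did not. No coordinates are given because the builds differ. Mitochondrially encoded transcripts had values for 0 of the 13 genes sought and are not analysed here.

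NADK2 and SMG1P3 stand more than once in the siRNA tables with different counts and were left out. The count of IL32 is blank in the library labelled JFK, so this gene has no fold there. Each count was checked against the value implied by its RPKM, its gene length and the depth that the table's own counts and RPKM imply, with a tolerance of 0.001 counts in the siRNA tables. For CHPF2 in the library labelled JFK the expected count is 9.96 times that implied by its FPKM, and for QSOX1 it is 1.22 times.

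Counts were scaled with TMM factors (log-ratio trim 0.3, intensity trim 0.05) computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; plots were drawn with matplotlib 3.10.9. Normalised counts were brought to the mean library size of the pair, 0.5 was added, and the log2 ratio was taken. A count test such as a quasi-likelihood fit needs replicates, so no test across genes was run and no p-value is given. The exact 95% Clopper-Pearson interval of the ratio of a pair of counts, with expected counts rounded to whole numbers, covers counting error only, since reads without molecular identifiers are not independent molecules. A gene was called measured with a mean normalised count of at least 20, and 2-fold was the threshold. Against a count of 0 the fold is a lower bound computed against a floor of 3 counts per library, equal to 0.418, 0.415, 0.326 and 0.332 CPM in vector, the library labelled JFK, control siRNA and ING5 siRNA.

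A total of 39 gene lists with 715 different genes, covering among others JFK and ING5 complexes, NF-kB and interferon targets, liver functions, metabolism, stress, the cell cycle and markers of other cell types, were fixed before the data were examined, as were the thresholds, the rule for named genes and all alternatives except those named as added. Members at least 1.5-fold apart were counted. A list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries; lists with fewer than 5 measured members have values only. Named genes were drawn from FBXO42, ING5 and ING4; the 12 higher and the 12 lower genes per comparison, among those at least 2-fold apart, whose interval bound lay farthest from 0; the 3 highest and 3 lowest members of each list described; and, for both comparisons together, 8 genes higher in both, 8 lower in both and 4 in each opposite direction. Examples are drawn from these, and some genes and lists that the rule covers are not reported here. Genes without a symbol were passed over. The number of genes expected in both comparisons is the product of the separate counts over the number of genes measured in both.

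The method was tested on simulated data, with counts drawn from the libraries' own means and 200 genes set at 3-fold. For the vector pair 98.5% of these were recovered at 2-fold among 12118 genes, with 7 unchanged genes called higher and 4 lower; for the siRNA pair 99% were recovered among 11637, with 6 and 4. At 1.5-fold 192 and 168 unchanged genes passed, so counting error alone gives calls at that threshold. The intervals held the true fold for 95.5% and 95.2% of genes, and 6% and 4.5% of unshifted lists fell outside the 2.5 to 97.5 percentiles. Counts were drawn independently as whole Poisson numbers around means shared by the pair, so coverage near 95% follows from the design. Variation between libraries, genes that vary together and divided reads were not simulated.

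Alternatives were median-of-ratios, total-count and upper-quartile scaling, no filter, a mean of at least 100, 5 added in place of 0.5, thinning to the shallower library, thresholds of 1.5-fold and 4-fold, and random lists matched over 10 bins. A further 3 were added after seeing the data. These were the deposited FPKM or RPKM with 0.5 added to each value, and genes with whole counts only. The last left out genes whose count and RPKM disagree in either siRNA table.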

Results

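RNA sequencing was carried out on 4 libraries of cells that the labels name HepG2, a human line derived from a liver tumour and widely used as a hepatocyte model. The groups held 1 library each. A pair of libraries came from cells given an empty vector or a FLAG-tagged plasmid for JFK, the older name of FBXO42, the substrate-binding F-box subunit of a ubiquitin ligase. The other pair came from cells given a control siRNA or an siRNA against ING5, a PHD-finger subunit of histone acetyltransferase complexes built on MOZ, MORF and HBO1. NADK2 and SMG1P3 were left out of the siRNA pair. Reads assigned to the genes used came to about 7179580 for vector, 7237320 for JFK, 9196980 for control siRNA and 9030080 for ING5 siRNA. The 10 most abundant genes took 4.23%, 4.48%, 5.48% and 5.69% of these reads. With 1 library per group no difference has a replicate check, and all intervals are exact 95% Clopper-Pearson intervals of the ratio of a pair of counts, which cover counting error only.

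The targeted genes were read first, since they check the labels. ING5 (Entrez Gene 84289) had 81 counts in the ING5 siRNA library and 144 in control siRNA, a normalised level of 57.0% (log2 fold −0.81, interval −1.23 to −0.41). FBXO42 (Entrez Gene 54455) had 115 counts in the library labelled JFK and 116 in vector, a fold of 1.01 (0.772 to 1.32). A higher FBXO42 transcript level was thus not seen where the label names overexpression, and this library is called the library labelled JFK throughout. In that library ING5 stood at 145 counts against 181 (log2 fold −0.29, interval −0.62 to 0.03). In the ING5 siRNA library FBXO42 stood at 97 counts against 115 (−0.23, interval −0.63 to 0.17). ING4, the closest relative of ING5, lay at 0.01 in the library labelled JFK and −0.05 under ING5 siRNA.

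**Figure D1:**
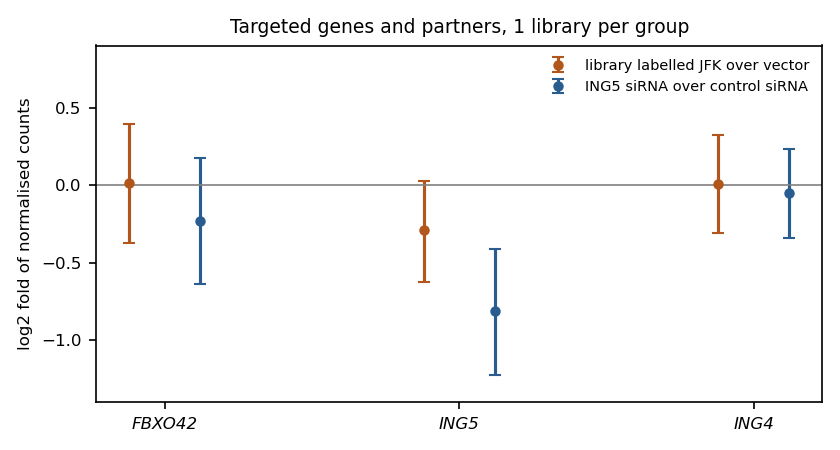
Log2 folds of normalised counts for FBXO42, ING5 and ING4 in both comparisons (points) with exact 95% counting intervals (bars), 1 library per group. ING5 under its siRNA lies at −0.81 with an interval that stays below 0, and FBXO42 in the library labelled JFK lies at 0.01.

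Most transcripts of proteins that hepatocytes secrete were near the detection floor in all 4 libraries. Of 25 such genes, 2 reached 20 counts in each library: VTN, for vitronectin, and RBP4, for the plasma retinol carrier. Apolipoprotein genes APOA1 and APOB had at most 2 and 1 counts, the alpha-fetoprotein gene AFP at most 1, and the antitrypsin gene SERPINA1 at most 7. The median of the listed members lay between 0.276 and 0.557 CPM (counts scaled by the library total), where 3 reads correspond to 0.326 to 0.418. Other liver-associated transcripts were present: the fetal RNA H19 had 26731 to 116351 counts, the urea-cycle enzyme gene CPS1 22227 to 46771 and HNF4A 51 to 91. Of 17 hepatocyte transcription factor genes, 9 had at least 20 counts in vector and in the library labelled JFK and 8 in each siRNA library. The complement gene C3 had 3145 to 5000 counts, the ceruloplasmin gene CP 1206 to 1412 and the transporter gene ABCC2 620 to 1226. Among genes typical of other carcinoma lines, the placental phosphatase gene ALPP, chosen after its values were seen, had 10851 to 26763 counts, and the basal keratin gene KRT17, of the breast line list, 2299 to 27539. Markers of further cell types were also read. Of the 13 breast carcinoma line genes 4 had at least 20 counts in vector, as did 4 of 11 fibroblast genes, 3 of 9 endothelial genes, 2 of 11 leukocyte genes and 3 of 10 genes of an embryonic kidney line.

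**Figure D2:**
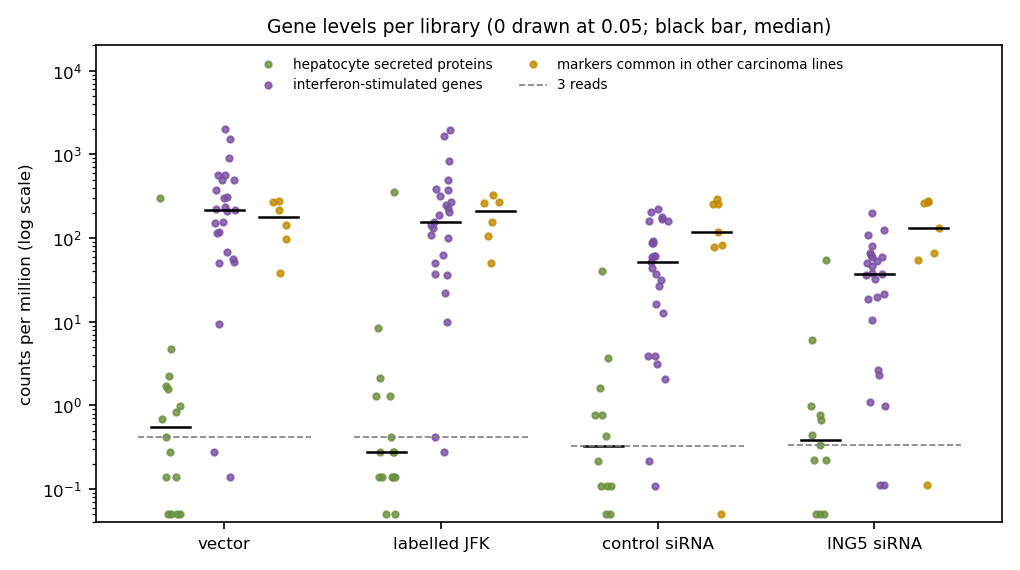
CPM on a log axis for hepatocyte secreted proteins, interferon-stimulated genes and markers common in other carcinoma lines in each library; points are genes, black bars medians and dashed lines the level of 3 reads. Medians of the hepatocyte secreted proteins lie between 0.276 and 0.557 CPM, while interferon medians run from 36.9 in ING5 siRNA to 215 in vector.

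Count and RPKM of the same gene did not match for part of the siRNA tables. Within 0.001 counts, the RPKM and gene length gave another count than the one listed for 37 genes in control siRNA and for 112 in ING5 siRNA, 109 of the latter with a listed count above the implied one. The median gap was 13.4% for the 37 and 2.24% for the 112, and among genes above 100 counts the largest was 16.1% and 13.2%. The 112 include CHPF2, QSOX1, KRT18, KRT7, NDRG1, TOP2A, OAS3 and DTX3L.

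The library labelled JFK was set against vector to ask which transcripts differ with the plasmid. Antiviral genes of the interferon response stood lower in it: the median of 23 measured interferon-stimulated genes was −0.40 on the log2 scale, below all 10000 random lists matched on expression (central 95% of these −0.04 to 0.13). Of the 23, 19 lay below 0, 17 had an interval wholly below 0, and 5 were at least 1.5-fold lower. Glycolytic genes lay slightly higher as a group, with a median of 0.18, while abundant non-coding RNAs had a median of −0.21. Differences of 2-fold or more were rare among genes with well-separated reads.

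Within the interferon list the lowest members were IFI44L, with 160 counts against 373 (log2 fold −1.19, interval −1.47 to −0.93), the RNA sensor gene IFIH1, with 449 against 851 (−0.90), and the oligoadenylate synthetase gene OAS2, with 948 against 1544 (−0.68). Not every member was lower. The ubiquitin-like modifier gene ISG15 had 11923 counts against 11061 (0.13, interval 0.10 to 0.17), MX1 lay at 0.11 and IFI27 at 0.07. The interferon-inducible apoptosis gene XAF1, outside the list, was among the genes farthest below vector, with 177 expected counts against 449 (−1.31, interval −1.58 to −1.06). The list median ran from −0.43 to −0.34 over the alternative settings, the latter with no filter and also without the genes whose count and RPKM disagree, which include OAS3 and DTX3L.

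Of 20 measured glycolysis genes, 18 lay above 0 and none was 1.5-fold apart (median 0.18, percentile 99.85 among random lists). PFKFB4, a regulator of the phosphofructokinase step, and SLC2A1, the glucose transporter GLUT1, both lay at 0.33, with intervals of 0.11 to 0.56 and 0.22 to 0.44. The mitochondrial gatekeeper kinase PDK1 lay at −0.19 (−0.44 to 0.06). Immediate early genes had a median of 0.15 (percentile 98.75), led by JUN with 120 counts against 79 (0.62, interval 0.21 to 1.06) and by CCN1, a secreted matrix protein, at 0.36 (0.26 to 0.46). Abundant non-coding RNAs lay lower, at a percentile of 0.06. Their list is labelled nuclear but also holds H19, GAS5, SNHG1 and SNHG5. The lowest were MALAT1, with 444 counts against 595 (−0.40), KCNQ1OT1 (−0.39) and the paraspeckle scaffold NEAT1, with 4124 against 5355 (−0.35, interval −0.41 to −0.29). Of 8 measured, 6 lay below 0 and none was 1.5-fold apart, while 1 of the 2 above 0 had an interval wholly above 0. Ribosomal RNA genes, chosen after their values were seen, differed in direction in the same library: RNA28SN5 had 26439.4 expected counts against 17283.2 (0.64) and RNA18SN5 15760.4 against 7998, while RNA45SN5 lay at 0.02 and RNA5-8SN5 at −0.99.

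The median of SCF subunits and substrate-linked genes was −0.04 and that of the ING family and its acetyltransferase partners 0.01. NF-kB target genes lay at 0.09 (percentile 88.8), with 1 of 15 at least 1.5-fold higher, the cytokine gene IL6 (0.68, interval 0.33 to 1.04). Hypoxia genes lay at 0.10 (percentile 95.3), where CA9 stood at 0.38 and NDRG1 at −0.57. Among metabolic lists the medians were 0.07 for cholesterol synthesis, −0.03 for fatty acid and triglyceride synthesis, −0.02 for fatty acid oxidation, 0.09 for lipid droplet genes and 0.01 for gluconeogenesis. Within them HMGCS1, which makes the precursor of mevalonate, had 804 counts against 1194 (−0.55), and the gluconeogenic enzyme gene FBP1 had 50 against 19 (1.40, interval 0.63 to 2.27). Growth and stress lists had medians of −0.02 for S phase genes, −0.02 for G2/M genes, 0.02 for replication-dependent histones, −0.01 for the unfolded protein response, 0.01 for ATF4 targets, 0.07 for heat shock proteins and 0.06 for NRF2 targets. The amino acid response genes ASNS and SLC7A11 lay at −0.51 and −0.50, and GDF15 at 0.47.

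In total 33 of 12107 measured genes were at least 2-fold higher and 36 at least 2-fold lower in the library labelled JFK, 0.570% of those measured, against 17 and 23 by FPKM and 5 and 3 at a mean of at least 100. Of these 69 genes, 49 had counts that were not whole numbers, as arises when reads are divided among overlapping or near-identical genes, against 33.8% of all measured genes. BOLA2, which has a near-identical copy, was at least 18.7-fold higher, and GTF2IP1, a pseudogene copy of GTF2I, at least 58.2-fold lower. Similar splits are open for INO80B, NOMO3, FAM72B, FAM72A, TMEM183BP, KLHL23, NBPF11, EIF3CL, FAM156B, ANXA8L1 and CORO7, and for the readthrough loci RAB4B-EGLN2, ARPIN-AP3S2, BORCS8-MEF2B, TMEM256-PLSCR3, ARL2-SNX15, TNFSF12-TNFSF13 and FMC1-LUC7L2, so these are reported as uncertain. Counting only genes with whole counts left 14 higher and 6 lower. CHPF2, a chondroitin polymerising factor gene, had 8053 counts against 1115 (log2 fold 2.88), yet its deposited FPKM was 27.8 against 38.8, so its direction turns with the unit. RNA18SN5, a ribosomal RNA gene copy, had 15760.4 expected counts against 7998 (counting interval of the log2 fold 0.96 to 1.04).

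ING5 siRNA was compared with control siRNA to ask which transcripts depend on ING5. NF-kB target genes stood higher as a list: CXCL8, for the neutrophil chemokine interleukin-8, had 94 counts against 7 (log2 fold 3.67, interval 2.66 to 5.12), and IL6 had 58 against 12. The median of 16 measured NF-kB target genes was 0.71, above all 10000 matched random lists. Interferon-stimulated genes stood lower, with a median of −0.72 and 14 of 22 at least 1.5-fold lower. Genes of gluconeogenesis, epithelial junctions, mitosis, WNT targets and histones also lay below their random lists.

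Of the NF-kB target genes, 9 were at least 1.5-fold higher and 1 was lower. IER3, a survival factor gene, had 2801 counts against 1352 (1.07, interval 0.97 to 1.16), and the exception was CCL2, the monocyte chemokine, with 20 against 44 (−1.10, interval −1.96 to −0.33). NFKB1, for the p105 precursor, lay at −0.07. The median ran from 0.58 to 0.77 over the alternatives. Beyond this list the genes farthest above control siRNA included IL7R, the interleukin-7 receptor, with 598 counts against 99 (2.60, interval 2.30 to 2.93), IL32, with 166 against 44 (1.92), IL1A, with 41 against 7, and OLR1, the oxidised LDL receptor, with 764 against 272. Of the 12 genes farthest above control siRNA, the matrix protein gene CCN1 had 5091 counts against 1990 (1.37), PDGFB 274 against 87 (1.67) and the membrane protease gene FAP 81 against 22 (1.87). PKD1L2 had 47 counts against 6 (2.88), and the endoplasmic reticulum protein gene RCN3 had 196 against 68 (1.54).

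Interferon-stimulated genes lay below all random lists, and 18 of 22 were below 0. The lowest were RSAD2, for viperin, with 9 counts against 36 (−1.93, interval −3.22 to −0.90), OASL with 543 against 1491 (−1.44) and IFIT2 with 719 against 1890 (−1.38). IFIT3, also among the 12 genes farthest below control siRNA, had 601 against 1460 (−1.26). Counter-examples were IFI6 at 0.25 and IFITM1 at 0.27. Over the alternatives the median ran from −0.73 to −0.69.

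**Figure D3:**
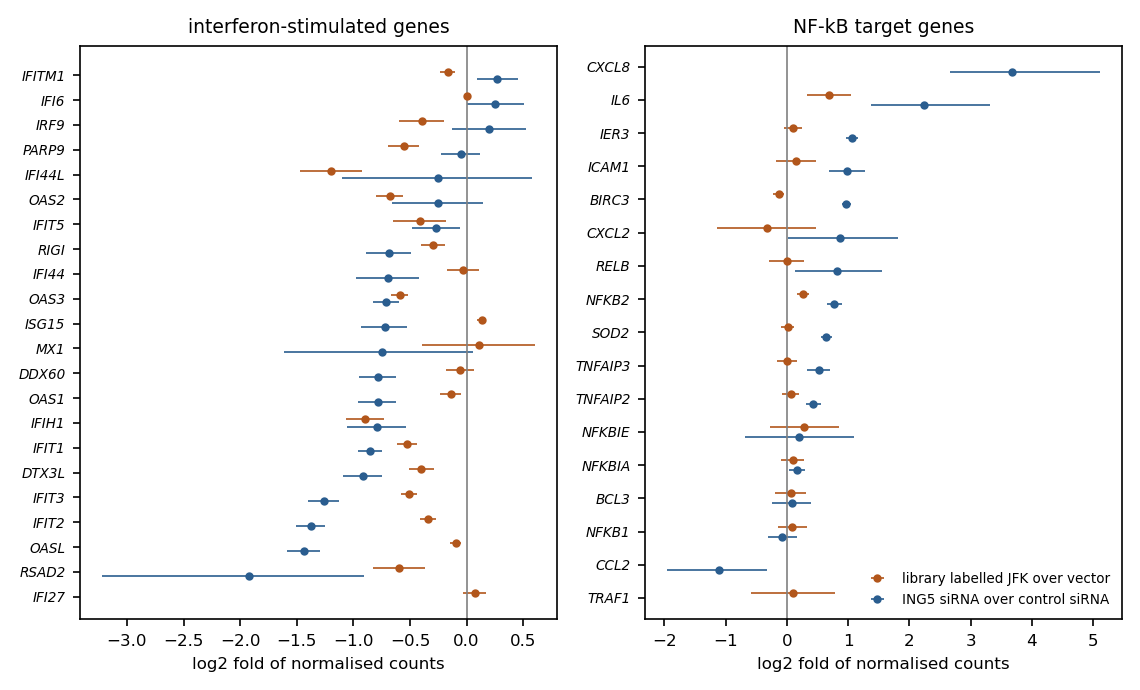
Log2 folds of normalised counts of interferon-stimulated genes and NF-kB target genes in both comparisons, with exact 95% counting intervals, 1 library per group. Most interferon genes lie below 0 in both comparisons (19 of 23 and 18 of 22 measured, 1 of which is not drawn), and 9 of 16 NF-kB target genes are at least 1.5-fold higher under ING5 siRNA.

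Among the 12 genes farthest below control siRNA, PSAT1, the serine-synthesis aminotransferase, had 483 counts against 1299 (−1.41, interval −1.56 to −1.26), NDUFAB1, the mitochondrial acyl carrier protein, 140 against 395 (−1.48) and HPD, a tyrosine-degrading dioxygenase, 170 against 429 (−1.32). Others were the transglutaminase gene TGM1 (31 against 118, −1.90), PDXP (−1.54), PDCD6 (−1.25), SELENOI (−1.25), the chromatin accessibility and DNA polymerase epsilon subunit POLE3 (−1.20) and AATK (−1.31). Gluconeogenesis had a median of −0.38 (percentile 0.05), with 9 of 10 genes below 0. Its lowest members were the glucose-6-phosphate transporter gene SLC37A4, with 65 counts against 129 (−0.97), the coactivator gene PPARGC1A, with 188 against 328 (−0.79), and PC, for pyruvate carboxylase (−0.57), while FBP1 had 36 against 18 (interval 0.16 to 1.92).

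Epithelial junction genes had a median of −0.30 (percentile 0.01), and 14 of 16 lay below 0, 1 was 1.5-fold higher and 0 were 1.5-fold lower. The tight junction gene TJP3 lay at −0.50 and the keratin gene KRT18 at −0.46, while EPCAM had 73 counts against 47 (0.65) and CLDN1 1329 against 1015 (0.40). Mitotic genes of the G2/M list had a median of −0.16 (percentile 0.21), with 23 of 25 below 0 and none 1.5-fold apart; cyclin B1, CCNB1, had 1534 counts against 2047 (−0.40, interval −0.50 to −0.30) and the topoisomerase gene TOP2A lay at −0.42. WNT targets had a median of −0.28 (percentile 1.1), with GLUL, for glutamine synthetase, at −0.64 and MYC at 0.13. The 5 measured replication-dependent histone genes had a median of −0.57, from H2AC6 at −0.89 to H1-2 at 0.49. Hypoxia genes lay above their random lists (0.15, percentile 99.5), with ADM, the vasodilator adrenomedullin, at 0.78 and EGLN3 at 0.50, against NDRG1 at −0.69. For KRT18, TOP2A and NDRG1 the count and RPKM disagree in the ING5 siRNA table.

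The ING family and acetyltransferase partners of ING5 had a median of −0.15 (percentile 4.84): ING1 had 1087 counts against 792 (0.47, interval 0.34 to 0.61), and JADE2, a scaffold of HBO1 complexes, 412 against 691 (−0.73, interval −0.91 to −0.55). SCF subunits and substrate-linked genes lay at −0.20 (percentile 4.72). Immediate early genes had a median of 0.13 (percentile 95.8), with 5 of 18 at least 1.5-fold higher and 1 lower. Further medians were 0.12 for mesenchymal genes, 0.07 for glycolysis, 0.10 for fatty acid and triglyceride synthesis and −0.10 for cholesterol synthesis. They were −0.11 for fatty acid oxidation, 0.11 for lipid droplet genes, −0.08 for S phase genes and 0.07 for the unfolded protein response. The rest were 0.03 for ATF4 targets, −0.09 for heat shock proteins, 0.06 for NRF2 targets and 0.01 for abundant non-coding RNAs. Within these lists, SNAI2, an epithelial-mesenchymal transition factor, had 120 counts against 232 (−0.93). HK2, for hexokinase, had 3755 against 2320 (0.71) and FASN, for fatty acid synthase, 5027 against 3505 (0.54).

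Of 11634 genes measured, 89 were at least 2-fold higher and 81 at least 2-fold lower under ING5 siRNA, 1.46% of those measured. The counts depend on the setting, with 39 higher and 39 lower by RPKM, and with 20 higher and 36 lower at a mean of at least 100. In the siRNA pair 8 of 31 lists lay outside the central 95% of random lists, where chance gives 1.55. In the vector pair 4 of 32 did, where chance gives 1.6. Between control siRNA and vector 7 of 31 did, where chance gives 1.55. The chance values take list members as varying independently, as the members of random lists are drawn. All these values describe a pair of libraries and not the conditions.

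**Figure D4:**
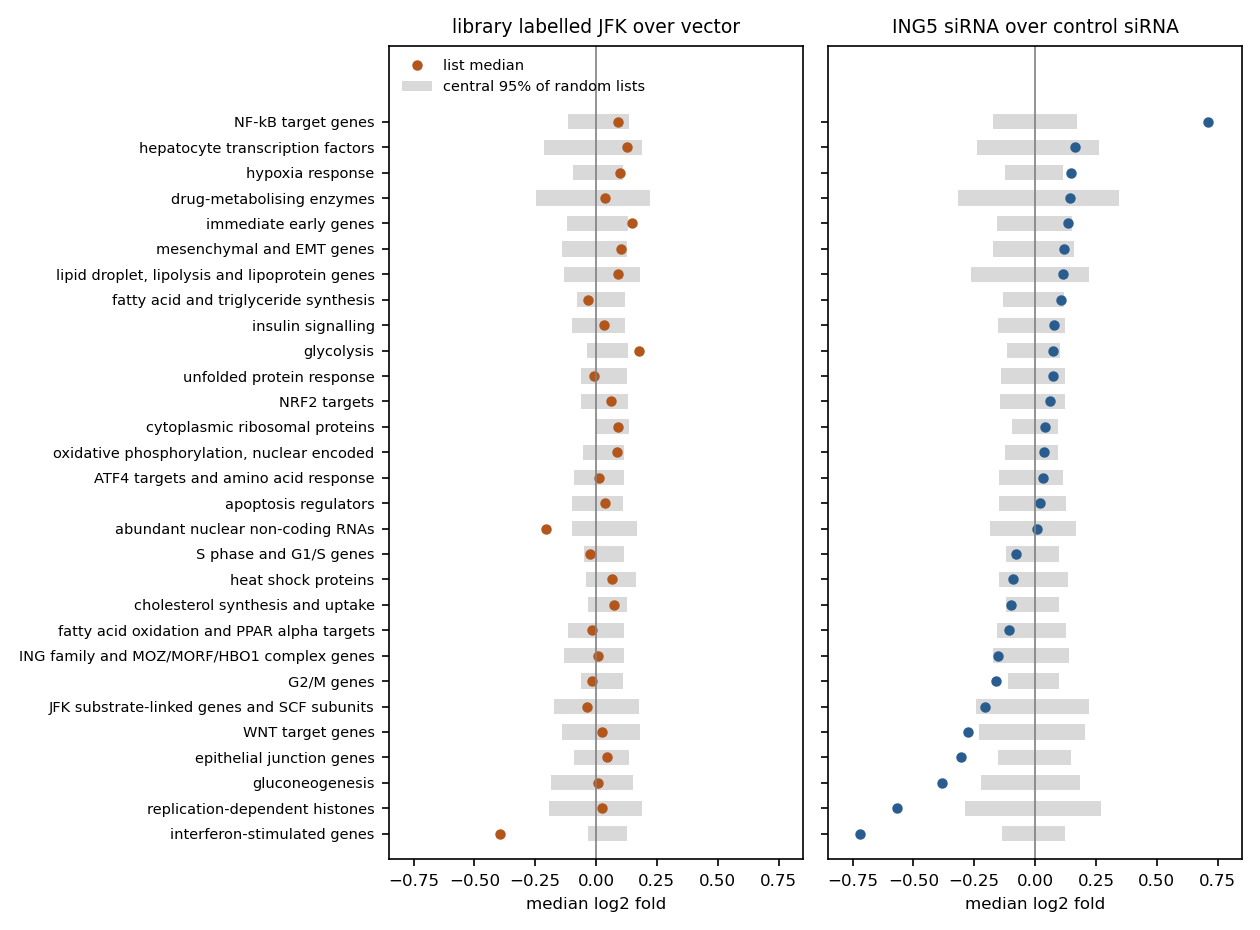
Median log2 fold of gene lists (points) with the central 95% of 10000 random lists matched on expression (grey bars), for the library labelled JFK over vector and ING5 siRNA over control siRNA, 1 library per group. Interferon-stimulated genes lie at −0.40 and −0.72, and NF-kB target genes at 0.09 and 0.71.

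The comparisons were then set side by side to ask whether the same transcripts differ with JFK and with less ING5, which have separate controls. Few genes were 2-fold apart in both: FAM72B and the vesicle-trafficking GTPase gene RAB3A were higher in both, where independent lists give 0.0582. FAM72B has a near-identical copy and stays uncertain, and the 2 genes become 1 with median-of-ratios scaling or whole counts only and 0 with 5 added, by FPKM and RPKM or at a mean of at least 100. None of 11148 genes was lower in both, where independent lists give 0.0947, and 1 gene lay in opposite directions, or 0 with whole counts only, by FPKM and RPKM or at a mean of at least 100. At 1.5-fold, 19 genes were higher in both (2.93 by independent lists), 23 lower in both (7.18) and 21 in opposite directions (9.30). The independent-list values take every measured gene as equally likely to pass. Genes with few counts pass more often by counting error in both pairs, and 192 and 168 unchanged genes passed in simulation. Opposite directions exceeded their value as well, so an excess alone shows no shared effect. The gluconeogenic FBP1 had 50 counts against 19 and 36 against 18, N4BP3 lay at 0.92 and 1.27 and TMEM156 at 0.89 and 1.27. On the lower side stood the zinc-finger gene ZNF93 at −0.81 and −1.13, IFIH1 at −0.90 and −0.79, CRIP2 at −0.93 and −0.77 and the keratin gene KRT7 at −0.67 and −0.84. For KRT7 the count and RPKM disagree in the ING5 siRNA table. In opposite directions lay the myosin gene MYO7A, at 0.80 and −0.80, the pro-apoptotic BIK, at 0.81 and −0.74, and ZNF449, at −0.85 and 0.79. Across genes, which are not independent replicates, the folds had a Pearson r of 0.0582 and a Spearman rho of 0.0253.

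Genes whose count and RPKM disagree in the ING5 siRNA table stood apart here. Of the 109 measured in both comparisons, 107 were lower in both, 98.2% against 25.2% of the 11039 other genes. Their median log2 fold was −0.47 in the library labelled JFK and −0.53 under ING5 siRNA. They made up 12 of the 23 genes at least 1.5-fold lower in both. Among 2873 genes with a mean of at least 500 counts in both comparisons, r was 0.160 with the 64 of them in that range and 0.0310 without; without the interferon list it was 0.146 over 2862 genes.

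**Figure D5:**
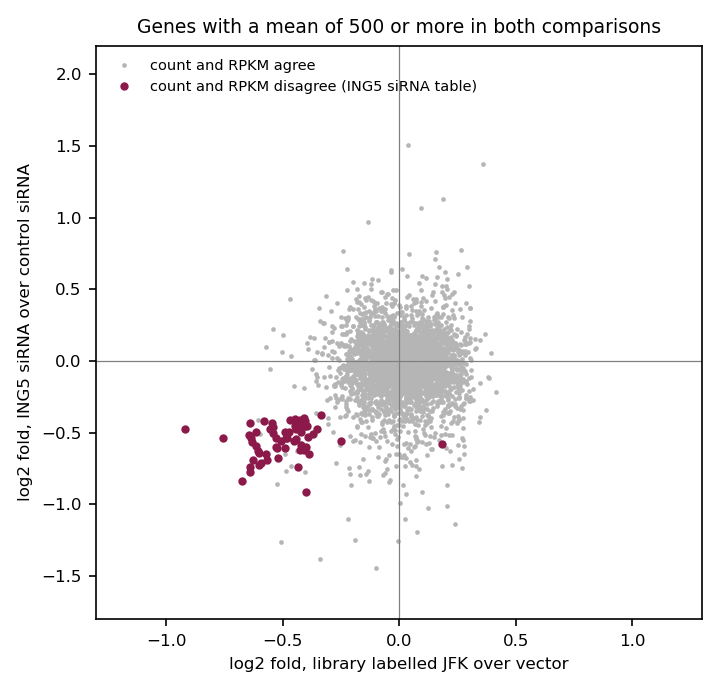
Log2 fold under ING5 siRNA against log2 fold in the library labelled JFK for 2873 genes with a mean normalised count of at least 500 in both comparisons; dark points are the 64 genes whose count and RPKM disagree in the ING5 siRNA table. Nearly all dark points fall in the lower left, and r is 0.160 with and 0.0310 without them.

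The controls, control siRNA and vector, were compared to gauge how far libraries given only control reagents differ in this series. They differed at 4017 of 12022 genes (33.4%) by 2-fold or more, 1905 higher and 2112 lower in control siRNA. Interferon-stimulated genes had a median of −1.67 in control siRNA over vector, and IFI6 had 245 counts against 14352. G2/M genes lay at 0.94 and hypoxia genes at 1.37. Reagent and the processing that gave each table differ along with the groups, so these cannot be told apart. Scaling also moved the split: 2039 higher and 2006 lower by median-of-ratios, 1370 higher and 2575 lower by total count, 1459 and 2493 by the upper quartile and 1081 and 2455 by FPKM and RPKM, which shift the median of all genes by 0.04, −0.17, −0.14 and −0.20.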

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

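The test of 7 further markers, chosen for a squamous-type line, was fixed before their levels were viewed. All other tests in this part were chosen only after the results were seen. A value outside the comparisons drew attention: the count of IL32 is blank in the library labelled JFK, while its FPKM there is 44.71 against 31.32 in vector, a ratio of 1.43.

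Most transcripts of hepatocyte secreted proteins lay near the floor in all 4 libraries. Too little sequencing is argued against, since 71.6% of all genes in the vector table reached 20 counts and 12.5% of the 16 secreted-protein genes in it did. Missing gene names are argued against only for the listed members, which had a median of at most 0.557 CPM. Of the 25 genes sought, 16 are listed in the vector pair and 12 in the siRNA pair. Only genes above 0 in at least 1 library of a pair are listed. For the rest a missing name and an absence of reads cannot be told apart. A candidate explanation is cells of another epithelial line. The markers (ANXA1, CAV1, CD44, AXL, CAVIN1, LGALS1 and KRT5) had library medians of 119 to 154 CPM. KRT5 had at most 1 count and was taken as 0 in the vector and JFK tables, which do not list it. Many non-hepatic lines share the markers, so they name no line and cannot tell an epithelial line from another. A loss of the hepatocyte program in HepG2 stays open and untested, and the counts of H19, CPS1, C3 and CP, with 9 of 17 hepatocyte transcription factor genes at 20 counts or more in vector, speak for some liver character.

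FBXO42 was not higher in the library labelled JFK. Too few reads cannot hide a 2-fold higher level of the transcripts counted, since the upper counting bound of the fold is 1.32. A swap with vector stays open with a lower bound of 0.772, because a plasmid transcript that is not counted would leave the fold near 1 under either labelling. A plasmid transcript that was not counted as FBXO42 may exist, and the fold of 1.01 does not decide, because the plasmid sequence and the reads are not used here. Whether the cells took up and expressed the plasmid at all was not tested and stays open as well.

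Genes whose count and RPKM disagree in the ING5 siRNA table were lower in both perturbed libraries. Errors that fell on genes at random are argued against, since 98.2% were lower in both against 25.2% of other genes. The gap between count and RPKM does not account for the lowering, since the median log2 fold of these genes by RPKM is −0.57. By count it is −0.53, and with a median gap of 2.24% these values had to lie close together. RPKM was deposited along with the counts, so whether both are at fault was not tested. Values of these genes may have been entered in the tables of both perturbed libraries apart from those of other genes: among genes with whole counts and an FPKM of at least 10, log2 ratios of JFK over vector by count and by FPKM differed by more than 0.002, after centring, for 67.9% of them (exact interval 53.7% to 80.1%) and for 27.3% of all other genes, but for 53.8% (37.2% to 69.9%) of the 39 other genes as low in JFK, so the test does not decide. A shared lowering of these transcripts, with an unrelated fault in the counts, stays open and untested.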

How the results depend on the processing

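The FPKM or RPKM, whole-count and disagreeing-gene settings were chosen only after the data were seen. List medians moved by at most 0.5 times the central 95% width of the random lists in 619 of 619 cases. Percentiles, rerun only with random lists matched over 10 bins, kept their side in 63 of 63. Of 4701 gene folds 4675 stayed within their counting interval, 25 moved beyond it and 1 reversed. No filter, a mean of at least 100, whole counts only and leaving out disagreeing genes do not alter a gene's fold. Their 480, 480, 399 and 462 gene folds thus could not move and test nothing. Of 96 counts of genes 53 stayed within 1.5 times and 43 did not; in order, these are given for JFK higher and lower, ING5 siRNA higher and lower, genes at least 2-fold different between control siRNA and vector, both higher, both lower and opposite directions. No filter gave 1035, 1181, 1374, 1232, 6157, 196, 204 and 359, since genes near 0 counts then enter. The 1.5-fold threshold gave 181, 251, 466, 512, 6967, 19, 23 and 21, and 4-fold gave 4, 7, 5, 0, 890, 0 for both higher and 0 for opposite directions. A mean of at least 100 gave 5, 3, 20 and 36, with 0 for both higher and 0 for opposite directions. FPKM or RPKM gave 17, 23, 39 and 39, with 0 and 0 likewise. This setting also reversed CHPF2, whose count and FPKM disagree in the library labelled JFK, to −0.47. In this setting 0.5 was added to the FPKM or RPKM itself, which draws folds of genes with low values towards 0. In the siRNA pair count and RPKM disagree for 37 and 112 genes, and leaving these out gave 89 higher and 80 lower. Disagreeing values thus do not account for the fall to 39 and 39 there. Total-count scaling, which like this setting uses no TMM factor, gave 96 and 77. The fall in the siRNA pair thus goes with the added constant. The cause of the other changes was not tested. Whole counts only gave 14 and 6 for JFK, 2676 for the controls, 1 for both higher and 0 for opposite directions; 30 of the 36 genes lower in JFK do not have whole counts. With 5 added, JFK lower came to 22 and both higher to 0; median-of-ratios scaling gave 1 for both higher. The correlation across genes of the JFK and ING5 siRNA log2 folds, 0.0582, became 0.0191 with no filter, 0.0840 at a mean of at least 100 and 0.0284 without the disagreeing genes. Constants of 0.1 and 1 were set for tables without counts and were not run, and no replicate could be left out with 1 library per group.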

Other observations

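Further gene lists, none with a median outside the central 95% of its random lists where these were drawn, held single members that were higher or lower under ING5 siRNA. Cholesterol genes went both ways around a median of −0.10: INSIG1, which retains the SREBP activator in the endoplasmic reticulum, had 4716 counts against 2849 (log2 fold 0.74, interval 0.68 to 0.81), while EBP, a sterol isomerase, had 1497 against 2552 (−0.75) and HMGCS1 1079 against 1557 (−0.51). Insulin signalling genes, with a median of 0.08, held IGFBP1, a binding protein of insulin-like growth factors, at 0.96 (58 counts against 30), and PIK3CA, the catalytic PI3-kinase subunit, at −0.74 (331 against 561). Apoptosis regulators had a median of 0.02: BIRC3, an inhibitor of apoptosis, had 4394 counts against 2272 (0.97, interval 0.89 to 1.04), the initiator caspase gene CASP9 158 against 355 (−1.15, interval −1.43 to −0.88) and BAD 38 against 78 (−1.01). The heat shock genes HSPA1A and HSPA1B, near-identical copies whose reads can be divided, lay at −0.86 and −0.72. CDH5, for VE-cadherin, had 87 counts against 224 (−1.34), and 995 in vector. Of 3 measured acute phase genes CFB, a complement factor, lay at 0.42 (median 0.27). The 4 measured bile acid genes had a median of −0.43, with the transporter ABCC2 at −0.67. Drug-metabolising enzymes had a median of 0.14 over 6 genes, hepatocyte transcription factors 0.16, nuclear-encoded oxidative phosphorylation 0.04 and ribosomal proteins 0.04.

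In the library labelled JFK the medians were 0.03 for insulin signalling, 0.03 for apoptosis regulators, 0.07 for acute phase genes and 0.02 for bile acid genes. They were 0.04 for drug-metabolising enzymes, 0.13 for hepatocyte transcription factors, 0.09 for oxidative phosphorylation and 0.09 for ribosomal proteins. Of lists described before for ING5 siRNA, mesenchymal genes lay at 0.10, epithelial junction genes at 0.05 and WNT targets at 0.02. Members at the edges were the pro-apoptotic BIK, with 54 counts against 31 (0.81, interval 0.16 to 1.51), and the smooth muscle gene TAGLN, with 51 against 31 (0.73). VTN had 2598 counts against 2156 (0.29) and RBP4 61 against 34 (0.86) in this library; under ING5 siRNA they lay at 0.39 and 0.68. These 2 are the measured hepatocyte secreted proteins, with medians of 0.58 and 0.54. Among other cell types, the breast line markers had medians of 0.08 in the library labelled JFK and 0.44 under ING5 siRNA, the fibroblast markers 0.10 and 0.05, the endothelial markers 0.02 and −0.78, the leukocyte markers −0.27 and −0.32, and the embryonic kidney line markers 0.00 and 0.06.

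The 112 genes of the ING5 siRNA table whose count and RPKM disagree include interferon-responsive genes outside the list that were chosen after their values were seen: EIF2AK2, HELZ2, PARP14, PLSCR1 and USP18. Only PLXNB2 and CHPF2 of the 109 measured ones were not lower in the library labelled JFK. The gene lengths used in both siRNA tables differed for 0 of the genes, and 3 of the 112 also disagree in the control siRNA table.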
